A study of Homo sapiens with 12 samples.

How the data were processed

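RNA from ECC1, a human endometrial cancer cell line, was measured on 12 Illumina whole-genome BeadArrays by direct hybridization of biotin-labelled material made from total RNA. The labels give a parental line and a line with MTDH knocked out. Each line was left untreated or given 10 nM estradiol for 24 h, after 24 h in RPMI1640 medium with 5% charcoal-stripped serum. The 4 groups held 3 arrays each. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Whether replicate numbers pair the arrays of different groups is not settled: of 18 same-numbered pairs, 6 had a correlation of residuals above 0.1. These correlations ranged from −0.4985 to 0.6467. Both extremes lay between the estradiol groups, where some arrays went against their labels, so the correlations cannot decide it.

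The deposited values are in log2 units, with 1 value per gene symbol or other identifier and array. The table had 34595 such entries, with 0 missing values, and each of its columns was mapped to a sample. Array medians lay between 6.78 and 6.86, minima between 6.30 and 6.42 and maxima between 14.6 and 14.9. The background correction, the normalization between arrays and the way in which probes were combined were not given in the sources used here. Of the identifiers, 17757 were current symbols, 3303 were older symbols of 1 gene, 150 could stand for several genes and 13385 had no match. Gene names are printed as the table gives them. The number of arrays limits the precision of every value.

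A gene was tested if its value exceeded the median of all values, 6.817, on at least 3 arrays, which left 19670 genes. The upper quartiles of the arrays lay within 0.197 of one another, and no further normalization was applied. A linear model with 1 mean per group was fitted with limma version 3.58.1 in R version 4.3.3, which left 8 residual degrees of freedom. Moderated statistics came from empirical Bayes with default settings. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, separately for each comparison, and an adjusted p under 0.05 was called. The 5 comparisons were knockout against parental without estradiol, the same with estradiol, estradiol against untreated in each line, and the interaction. The interaction is the estradiol response of the knockout line minus that of the parental line. Changes are log2 differences with standard errors (SE).

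Before the data were examined, 30 gene lists, the filter, the comparisons, the alternative settings and the rule for naming genes were fixed. The lists cover hormone response, the cell cycle, cell adhesion, signalling, metabolism, immune genes and markers of other cell types. A total of 24 list members were found under an older symbol, and 1 member, CDK1, was not matched, because its older symbol CDC2, which the table holds, is also an older name of POLD1. Each list was tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Lists with fewer than 5 tested members were counted but not tested, which left 145 list tests. Those p-values were adjusted over the 145 tests. Members were also adjusted over the list alone.

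MTDH and ESR1 were named in each comparison. For each pair of groups, the 8 largest rises and 8 largest falls were named among genes called with no overlap between the 3 values of each group. For the interaction, the 6 called genes with the largest difference on either side were named, whether or not values overlapped. For each list called by camera, and for 11 lists in every comparison, the 4 members with the smallest p were named. A few genes beyond this rule are marked in the text as chosen after their values were seen.

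Alternatives were no filter, a filter at the 67th percentile, quantile normalization, centring of each array on its median, and a fit of the 6 arrays compared. Others were a trended and robust prior, array weights, the replicate number as a block, a minimum change of 1.5-fold, and a threshold of 0.01. Each of the 12 arrays was also left out in turn. After the data were examined, 2 arrays whose MTDH level went against their labels were left out together, with and without quantile normalization. That fit of 10 arrays left 6 residual degrees of freedom. Labels were never changed. Alternatives for combining probes and for a pseudocount did not apply, since the values were already logged and combined.

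The pipeline was checked on simulated data with 200 changed genes among 19670. The spreads came from the fit without the 2 arrays, and every simulated array followed its label. Recovery with 12 arrays therefore does not describe the real fit of 12 arrays, whose spread was wider. With 12 arrays, 98% of genes changed by 1.5-fold were recovered between the untreated lines, 92% for estradiol in parental cells and 84% for the interaction. With 10 arrays, the interaction recovered 56% of 1.5-fold and 98% of 2-fold changes. Python version 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures. The order of genes along chromosomes came from the GRCh38.p14 RefSeq annotation and was used for neighbour order alone.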

Results

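Gene expression was compared in the endometrial cancer line ECC1 with and without MTDH, in the absence and presence of estradiol. MTDH (metadherin, also called AEG-1) is a membrane-associated protein known from several cancers. Estradiol is known to act through the estrogen receptor encoded by ESR1, and which receptor carried the response in these cells was not tested. The 4 groups, parental and knockout, each untreated or given 10 nM estradiol for 24 h, held 3 arrays each. The knockout was represented by 1 line, so differences between lines hold the effect of MTDH loss together with any difference of that clone.

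MTDH was 11.13 on average (log2) in untreated parental cells and 8.56 in untreated knockout cells. It was lower by −2.57 ± 0.58 (SE, n = 3 per group, adjusted p = 0.016) in the knockout line, and the 3 knockout arrays lay below the 3 parental arrays. The 5 arrays labelled knockout with the low level still read MTDH at the 82.8 to 84.0 percentile of their own values, and the table does not say which part of the transcript was probed. With estradiol the labelled groups did not separate (−0.94 ± 0.58, adjusted p = 0.90). The array labelled parental estradiol replicate 3 read 8.97, near the knockout level, and the array labelled knockout estradiol replicate 1 read 10.94, near the parental level. The profile of each across genes was also closest to arrays of the other line: 0.9965 (Pearson's r across genes, which are not independent replicates) between parental estradiol 3 and knockout estradiol 3, and 0.9967 between knockout estradiol 1 and parental estradiol 2. The labels were kept, and the number of genes called in each comparison is given again without these 2 arrays, an alternative chosen after the data were examined. Counts within gene lists are from all arrays unless stated. Without them, MTDH was −2.57 ± 0.11 (adjusted p = 5.2e-11) untreated and −2.40 ± 0.14 (adjusted p = 2.8e-09) with estradiol. Estradiol itself left no detected difference in MTDH in parental (−0.88, adjusted p = 0.44) or knockout cells (0.75, adjusted p = 0.60), or without the 2 arrays (−0.24, adjusted p = 0.26, and −0.07, adjusted p = 0.86). The untreated difference missed the threshold with a trended and robust prior (adjusted p = 0.0668), and when any of 4 arrays was left out: parental untreated 1 (adjusted p = 0.061) or 2 (0.066), or knockout untreated 2 (0.0669) or 3 (0.0585).

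**Figure D1:**
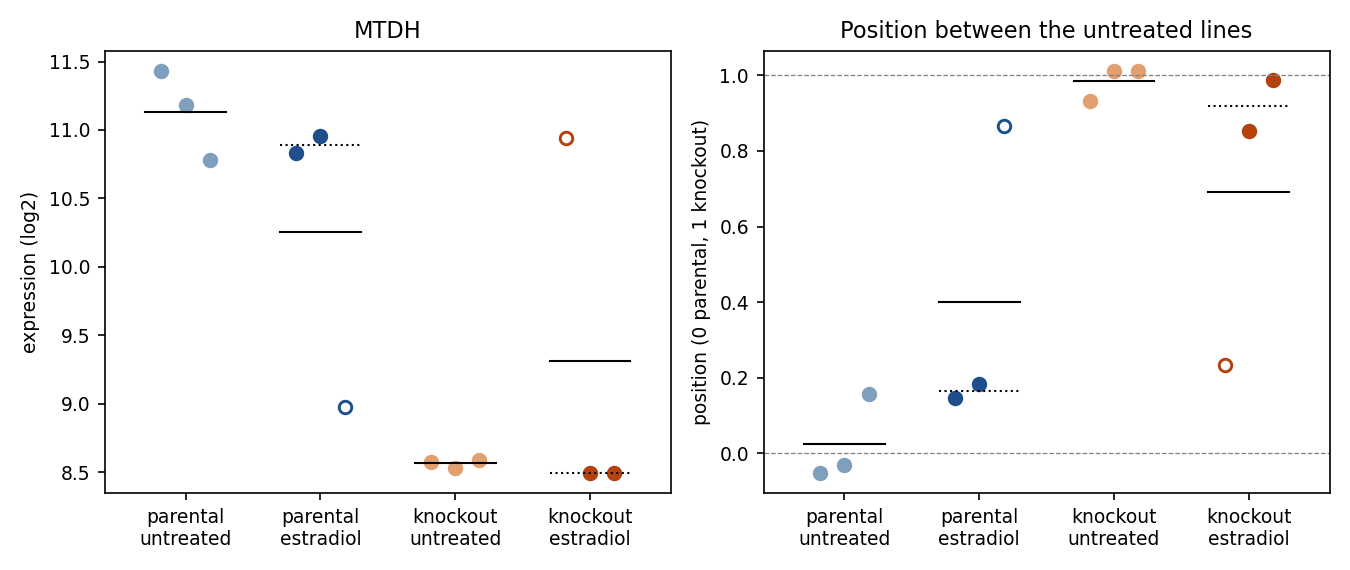
MTDH expression (log2, left) and position of each array on the axis between the untreated lines over 3800 genes (0 parental mean, 1 knockout mean, right), 1 point per array, in replicate order within each group. Solid bars are group means, open symbols are the 2 arrays whose MTDH went against their labels, at positions 0.865 and 0.235, and dotted bars are means without them.

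The first comparison asked what differed between the lines before estradiol. Several genes were far lower in the knockout line, led by the gene for a secreted protein. SPON1, a secreted matrix protein, went from 12.30 to 6.78 (−5.52 ± 1.36, n = 3 per group, adjusted p = 0.023). The membrane mucin MUC16 (−3.79 ± 0.91, adjusted p = 0.021), the serine protease TMPRSS2 (−2.81 ± 0.67, adjusted p = 0.020), the iron-carrier-binding LCN2 (−2.81 ± 0.65) and the phosphate transporter SLC34A2 (−2.72 ± 0.58) fell with it. MAL (−3.25), a protein of apical membrane sorting, LEFTY2 (−2.98), a secreted inhibitor of nodal signalling, and GDPD5 (−2.68) completed the 8 largest falls, of which MAL (adjusted p = 0.073) and LEFTY2 (adjusted p = 0.058) missed the threshold after quantile normalization. The largest rise was in ALDH3A1, an aldehyde dehydrogenase, from 9.41 to 11.91 (2.50 ± 0.58, adjusted p = 0.019). SERPINE2, a protease inhibitor (2.48 ± 0.65), ID3 (2.16 ± 0.46) and SMAD6 (1.52 ± 0.28), both typical targets of BMP signalling, the smooth muscle actin ACTA2 (1.67), the receptor KIT (1.67), CD24 (1.60) and SRPX (1.75) also rose.

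**Figure D2:**
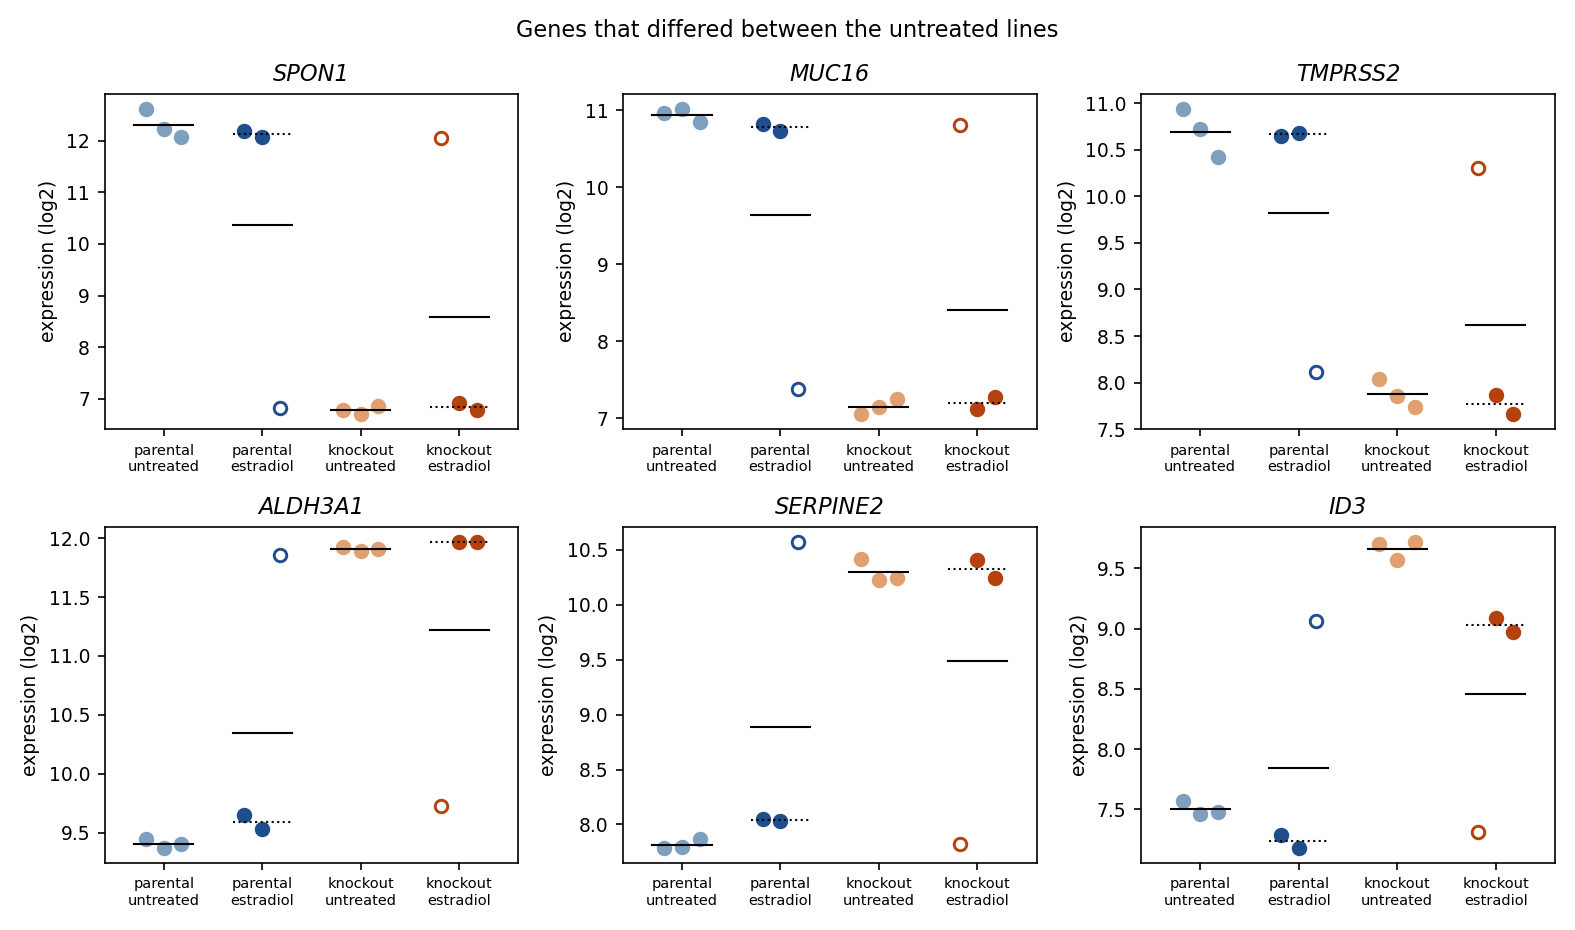
Expression (log2) on each array of 3 genes lower and 3 genes higher in untreated knockout cells, 1 point per array in replicate order, with solid bars for group means. Open symbols are the 2 estradiol arrays whose MTDH went against their labels, and dotted bars are means without them: for SPON1 the untreated means were 12.30 and 6.78.

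In total, 2152 of 19670 genes differed between the untreated lines, 454 higher and 1698 lower in knockout cells, so 21.1% of the calls were rises. That excess of falls was absent after quantile normalization, where 883 of 1582 calls were rises (55.8%). Quantile normalization gives all arrays the same distribution, so it cannot tell scaling from a true excess. After median centring the excess stayed, with 514 rises and 2551 falls (16.8% rises). Without the 2 arrays, which do not belong to these groups, the changes in the deposited values were identical and the smaller pooled spread gave 3844 genes, 1176 higher and 2668 lower. Leaving out single arrays gave between 435 and 2826 genes, the fewest without the array labelled parental untreated replicate 2.

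Many genes of cell division were lower in the untreated knockout line. Of 36 tested genes of mitosis, 18 fell and 0 rose (0 up and 31 down adjusted over the list alone), among them NDC80 (−0.53), TPX2 (−0.49) and KIF20A (−0.36), which act on kinetochores and the spindle, and CCNB1 (−0.35), the mitotic cyclin. The list was shifted down by camera (median −0.28, adjusted p = 1.1e-11; adjusted p = 0.564 with an estimated correlation). Of 39 tested genes of DNA replication, 9 fell and 0 rose (0 up and 19 down adjusted over the list alone), including RRM2 (−0.69) and TK1 (−0.41), which supply nucleotides, RFC3 (−0.71) and the helicase subunit MCM6 (−0.28). Camera put that list down as well (median −0.21, adjusted p = 4.6e-06; adjusted p = 0.675 with an estimated correlation). Genes of DNA crosslink repair and homologous recombination were down in 4 of 33 (0 up and 4 down adjusted over the list alone), namely UBE2T (−0.43), XRCC2 (−0.42), FANCI (−0.30) and FANCD2 (−0.32). That shift (median −0.10, camera adjusted p = 0.015; adjusted p = 0.773 with an estimated correlation) missed the threshold after quantile normalization (adjusted p = 0.11), where UBE2T and XRCC2 alone of the 4 were still called. After quantile normalization the medians were smaller in size, −0.152 for mitosis (adjusted p = 5.7e-06) and −0.0751 for replication (adjusted p = 0.0066). With the 2 arrays left out, 26 of the mitosis and 15 of the replication genes fell.

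Several epithelial adhesion genes were lower and several mesenchymal and TGF-beta genes were higher. Of 30 tested epithelial junction genes, 9 fell and 0 rose (1 up and 16 down adjusted over the list alone), among them the keratin KRT19 (−0.86), the transcription factor ELF3 (−0.46), the tricellular junction protein MARVELD2 (−0.50) and the desmosomal PKP2 (−0.44). Camera called the list down (median −0.25, adjusted p = 0.00020; adjusted p = 0.773 with an estimated correlation), with a median of −0.139 after quantile normalization (adjusted p = 0.0125). Of 20 mesenchymal genes, 4 rose and 2 fell (9 up and 3 down adjusted over the list alone): the integrin ITGB3 (0.53), the hyaluronan receptor CD44 (0.44) and the actin-binding TAGLN (0.88) rose, while vimentin, VIM, fell (−0.33). The list as a set was up (median 0.17, camera adjusted p = 0.0026; adjusted p = 0.564 with an estimated correlation), with a median of 0.275 after quantile normalization. Of 20 targets of TGF-beta and BMP, 7 rose and 4 fell (9 up and 4 down adjusted over the list alone), with rises in CTGF (0.99), TGFB2 (0.42) and the receptor decoy BAMBI (1.33) and a fall in the nodal inhibitor LEFTY1 (−1.17). Its camera shift was up (median 0.27, adjusted p = 0.0014; adjusted p = 0.564 with an estimated correlation). Of 17 fibroblast and stromal markers, 7 were expressed enough to test, and 2 of these rose, the collagens COL5A1 (0.89) and COL1A1 (0.52), with 3 up and 0 down adjusted over the list alone (median 0.14, camera adjusted p = 0.0038; adjusted p = 0.564 with an estimated correlation).

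Some genes of antigen presentation were higher in the untreated knockout line. Of 14 tested genes, 4 rose and 0 fell (8 up and 2 down adjusted over the list alone): the class I genes HLA-B (0.52) and HLA-E (0.80) and the class II loading factors HLA-DMA (0.78) and HLA-DMB (0.52). Camera put the list up (median 0.26, adjusted p = 0.00021; adjusted p = 0.713 with an estimated correlation). Interferon-response genes shifted up slightly (median 0.05, or 0.0808 after quantile normalization; camera adjusted p = 0.0097; adjusted p = 0.807 with an estimated correlation), with IFITM1 (0.53) and IFI6 (0.50) called among 27 (2 up and 0 down adjusted over the list alone). Of 25 cholesterol synthesis genes, 9 fell and 0 rose (1 up and 13 down adjusted over the list alone), among them FDFT1 (−0.33), FDPS (−0.40), ACAT2 (−0.36) and SC4MOL (−0.62). The shift of that pathway (median −0.27, camera adjusted p = 0.0023; adjusted p = 0.741 with an estimated correlation) missed the threshold after quantile normalization (−0.12, adjusted p = 0.065). Immediate early genes were mixed, with 3 up and 1 down of 27 (3 up and 1 down adjusted over the list alone), CYR61 (0.55) rising and EGR1 falling (−0.79). The set was up (median 0.06, camera adjusted p = 0.032; adjusted p = 0.807 with an estimated correlation).

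Estrogen-related and MTDH-linked lists did not shift as sets in the untreated lines. Of 38 genes raised by estrogen in earlier knowledge, 1 rose and 7 fell (1 up and 10 down adjusted over the list alone; median −0.10, camera adjusted p = 0.322). Among them CCND1, cyclin D1 (−0.71), the protease PRSS23 (−1.09) and AGR2 (−1.76), a disulfide isomerase of secretory cells, fell, and FHL2 rose (0.60). Genes lowered by estrogen counted 1 up and 3 down of 16 (1 up and 4 down adjusted over the list alone; camera adjusted p = 0.94). ESR1 differed by −0.28 (adjusted p = 0.063), or with adjusted p = 0.011 without the 2 arrays. Of 30 nuclear receptors and cofactors, RXRA (0.67) and NR1H3 (0.33) rose and NRIP1 (−0.53) and NR2F6 (−0.38) fell (2 up and 3 down adjusted over the list alone; camera adjusted p = 0.594). Of 13 genes linked to MTDH, 3 rose and 2 fell (4 up and 4 down adjusted over the list alone; camera adjusted p = 0.815). The rises included ALDH3A1, the largest rise between the untreated lines, and the drug efflux pump ABCB1 (0.67, adjusted p = 0.018). The falls were FANCD2 and FANCI, which also belong to the list of DNA crosslink repair. Among 20 targets of NF-kappaB, a pathway tied to MTDH, NFKB1 (−0.28, adjusted p = 0.014) and TNFAIP2 (−0.27, adjusted p = 0.028) fell and 0 rose (camera adjusted p = 0.827).

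The same comparison in estradiol asked whether the lines differed under hormone. With the labels as deposited, limma called 0 genes, and 1064 had an unadjusted p under 0.05. SPON1 stood at −1.78 ± 1.36 (adjusted p = 0.91) and ALDH3A1 at 0.87 ± 0.58 (adjusted p = 0.91). Camera still shifted DNA replication (adjusted p = 0.0086), mitosis (0.016), epithelial junction (0.0021) and cholesterol synthesis (0.0046) down and ribosomal proteins up (0.0070), without a called member. With an estimated correlation their adjusted p lay between 0.773 and 0.923, and after quantile normalization epithelial junction (0.0126) and cholesterol synthesis (0.032) alone stayed under the threshold.

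Without the 2 arrays, which left 2 arrays in each estradiol group, many of the largest differences between the untreated lines were also called in estradiol. SPON1 (−5.28 ± 0.13, adjusted p = 7.6e-14), MUC16 (−3.58 ± 0.09), MAL (−3.79 ± 0.10), LEFTY2 (−3.17 ± 0.17) and TMPRSS2 (−2.90 ± 0.13) were lower in knockout cells. The gel-forming mucin MUC5AC (−3.21 ± 0.09), the collagen COL6A1 (−2.85 ± 0.11) and the receptor TNFRSF14 (−2.80 ± 0.10) joined them. ALDH3A1 (2.38 ± 0.07, adjusted p = 1.3e-12), SERPINE2 (2.28 ± 0.09), ACTA2 (1.91), ID3 (1.80) and KIT (1.58) were higher, along with BEX1 (1.74), TMSB15A (1.63) and TCEAL2 (1.56). In all, 1926 genes differed, 976 higher and 950 lower. Of 3844 genes called without estradiol in this fit, 1271 were called in the same direction with estradiol and 12 in the opposite direction, where 187 in the same direction would be expected if the calls were independent.

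Some gene groups also separated the lines in estradiol once the 2 arrays were left out, and others did not. Mitosis genes counted 2 up and 1 down of 36 (3 up and 2 down adjusted over the list alone; camera adjusted p = 0.119), and neither ribosomal proteins (camera adjusted p = 0.648) nor mesenchymal genes (camera adjusted p = 0.35) were called as sets. Epithelial junction genes counted 0 up and 7 down of 30 (1 up and 14 down adjusted over the list alone), with CLDN7 (−0.80), EPCAM (−0.56) and KRT19 (−0.53) lower (median −0.22, camera adjusted p = 2.3e-06). Antigen presentation counted 6 up and 0 down of 14 (6 up and 0 down adjusted over the list alone), with HLA-E (0.63), HLA-DMA (0.60), CD74 (0.49) and PSMB10 (0.48) higher (median 0.17, camera adjusted p = 0.0014). TGF-beta and BMP targets counted 9 up and 3 down of 20 (9 up and 3 down adjusted over the list alone), with BAMBI (1.32) and SMAD6 (1.07) higher (median 0.17, camera adjusted p = 0.0023). Cholesterol synthesis counted 1 up and 7 down of 25 (2 up and 7 down adjusted over the list alone), with EBP (−0.75), SC4MOL (−0.74) and NSDHL (−0.57) lower (median −0.17, camera adjusted p = 0.00041). DNA replication shifted down (median −0.05, camera adjusted p = 0.0079), with 1 up and 5 down of 39 (2 up and 7 down adjusted over the list alone) and RFC3 at −0.83. Each of the called list shifts had an adjusted p between 0.981 and 0.984 with an estimated correlation.

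The next comparison asked what estradiol changed in parental cells. THBS1, the matrix glycoprotein thrombospondin 1, rose by 3.24 ± 0.10 (n = 3 per group, adjusted p = 4.3e-10), and SLCO2A1, a prostaglandin transporter, by 3.24 ± 0.09 (adjusted p = 2.1e-10). ALPPL2, an alkaline phosphatase (3.59 ± 0.16), DHRS3, a retinal reductase (2.99 ± 0.23), melanophilin, MLPH (2.37 ± 0.42), the calcium channel subunit CACNA1I (2.07 ± 0.08), the lipase inhibitor G0S2 (2.01 ± 0.08) and the plasminogen activator PLAT (1.87 ± 0.21) rose too. IGFBP3, which binds insulin-like growth factors, fell by 1.73 ± 0.10 (adjusted p = 3.7e-07). The keratins KRT17 (−1.59 ± 0.17) and KRT80 (−1.37 ± 0.06), the sterol exporter ABCA1 (−1.50 ± 0.12), TMTC1 (−1.32), the homeobox gene MEOX1 (−1.23), AFAP1L2 (−1.19) and EMP1 (−1.16) were the other large falls, and AFAP1L2 missed the threshold after quantile normalization (adjusted p = 0.052). The array labelled parental estradiol replicate 3, which carried the knockout profile, is included in these changes. KRT17 read 7.28 on it, against 8.02 and 7.99 on parental estradiol 1 and 2.

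**Figure D3:**
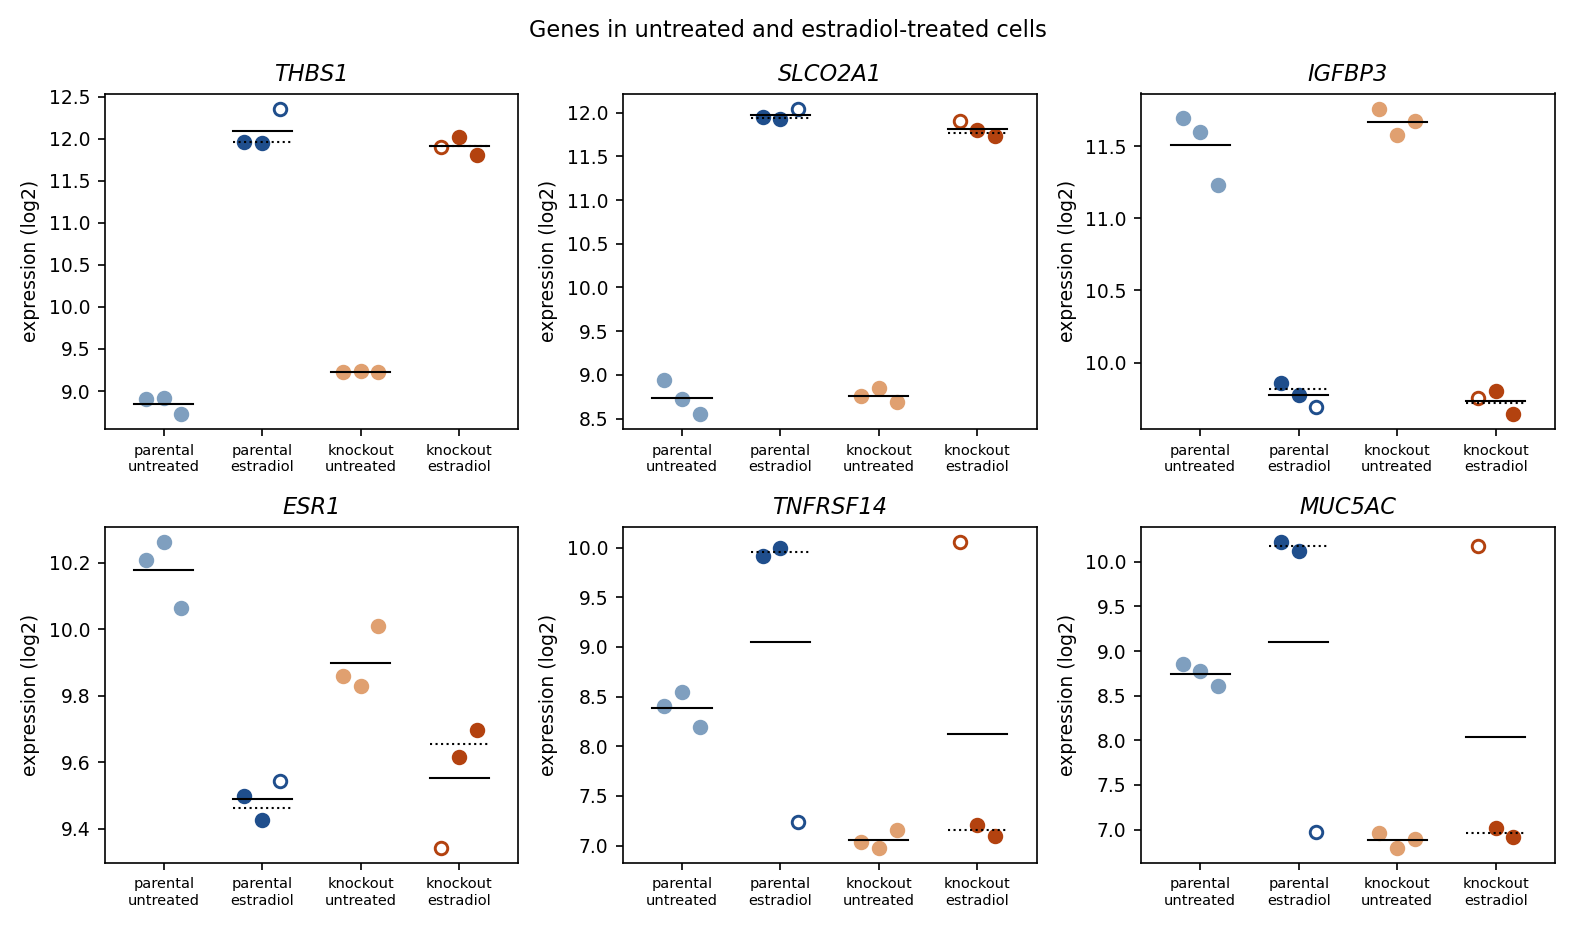
Expression (log2) on each array of 6 genes in untreated and estradiol-treated cells of both lines, 1 point per array in replicate order, with solid bars for group means. Open symbols are the 2 estradiol arrays whose MTDH went against their labels, and dotted bars are means without them: THBS1 rose by 3.24 in parental and by 2.68 in knockout cells.

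Both lists of estrogen-regulated genes shifted in parental cells. Of 38 genes raised by estrogen, 13 rose and 3 fell (13 up and 3 down adjusted over the list alone), among them the carbonic anhydrase CA12 (1.20), the amino acid transporter SLC7A5 (1.05) and the growth factor TGFA (1.33), while ELF3 fell (−0.79). The list was up by camera (median 0.07, adjusted p = 4.9e-06; adjusted p = 0.564 with an estimated correlation), with a median of 0.137 after quantile normalization and 0.0147 without the 2 arrays. Of 16 genes lowered by estrogen, 7 fell and 0 rose (0 up and 10 down adjusted over the list alone), among them TP53INP1 (−0.70), YPEL3 (−0.41) and the cell death gene BMF (−0.28), and the set was down (median −0.29, camera adjusted p = 4.8e-05; adjusted p = 0.564 with an estimated correlation). ESR1 itself fell (−0.69 ± 0.09, adjusted p = 0.00059), as did RXRB (−0.32), while the cofactor NRIP1 (0.48) and the membrane estrogen receptor gene GPER (0.55) rose among 30 nuclear receptors and related genes (4 up and 2 down over all genes, 4 up and 5 down adjusted over the list alone).

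Some cell division and epithelial adhesion genes were lower after estradiol in parental cells. Of 36 mitosis genes, 18 fell and 0 rose (0 up and 23 down adjusted over the list alone), including BUB1B (−0.60), TPX2 (−0.52), NUSAP1 (−0.38) and KIF20A (−0.38), and the set was down (median −0.26, camera adjusted p = 1.1e-08; adjusted p = 0.564 with an estimated correlation), with a median of −0.147 after quantile normalization (adjusted p = 1.5e-05). Of 39 replication genes, 4 fell and 0 rose (1 up and 14 down adjusted over the list alone), namely TK1 (−0.59), RRM2 (−0.58), MCM5 (−0.39) and MCM2 (−0.34). That shift (median −0.16, camera adjusted p = 0.0024; adjusted p = 0.807 with an estimated correlation) missed the threshold after quantile normalization (−0.0536, adjusted p = 0.068) and without the 2 arrays (adjusted p = 0.069). Of 30 epithelial junction genes, 13 fell and 0 rose (0 up and 16 down adjusted over the list alone), among them plakoglobin, JUP (−0.88), claudin 1, CLDN1 (−0.66), and the transcription factors ELF3 (−0.79) and GRHL2 (−0.63), with the set down (median −0.28, camera adjusted p = 1.3e-06; adjusted p = 0.675 with an estimated correlation). Genes of the unfolded protein and integrated stress responses were higher relative to the other genes, most of whose calls were falls (median 0.02, camera adjusted p = 0.0011; adjusted p = 0.773 with an estimated correlation), with 3 up and 2 down of 38 (4 up and 4 down adjusted over the list alone): SLC3A2 (0.73) and CEBPB (0.52) rose and CBS fell (−0.39). Tested against no change by fry, that list was not called (adjusted p = 0.54), and its median was 0.123 after quantile normalization and −0.0149 without the 2 arrays. Falls were also called in the interferon-induced IFITM2 (−0.50) and IFITM3 (−0.55) and in NFKB1 (−0.31) and TNFAIP2 (−0.42), while PTGS2, the inducible cyclooxygenase, rose (0.64) and neither the interferon list (0 up and 2 down, camera adjusted p = 0.698) nor the NF-kappaB list (1 up and 3 down, camera adjusted p = 0.946) shifted.

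Estradiol changed 1376 genes in parental cells, 221 up and 1155 down (16.1% rises). After quantile normalization 415 of 886 calls were rises (46.8%), which cannot tell scaling from a true excess of falls. After median centring the excess stayed, with 253 rises and 1446 falls. Leaving the 2 arrays out gave 2114 genes, 317 up and 1797 down, and the median change of the more strongly expressed genes (above the 67th percentile) was −0.118 there, against −0.0902 with all arrays. Single arrays left out gave 508 to 1707 genes, the fewest without the array labelled parental untreated replicate 2. These untreated parental arrays also enter the comparison of the untreated lines, so falls or rises shared by both comparisons hold shared chance values.

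In knockout cells, estradiol raised many genes that it also raised in parental cells. SLCO2A1 rose by 3.05 ± 0.09 (n = 3 per group, adjusted p = 4.6e-10), THBS1 by 2.68 ± 0.10 (adjusted p = 5.2e-09), DHRS3 by 3.22 ± 0.23 (adjusted p = 3.3e-06) and ALPPL2 by 2.91 ± 0.16 (adjusted p = 2.0e-07). The chloride channel gene listed both as TMEM16A (3.09 ± 0.38) and ANO1 (2.69 ± 0.45), GDPD5 (2.55 ± 0.54) and MLPH (2.19 ± 0.42) rose too. These changes include the array labelled knockout estradiol replicate 1, which carried the parental profile. For genes that differed between the untreated lines, such as GDPD5, they can hold part of that difference. Without the 2 arrays against their labels, the response of MLPH in knockout minus parental cells was −1.265. IGFBP3 fell by 1.94 ± 0.10 (adjusted p = 2.0e-07). The sterol exporter ABCA1 (−1.49), the matricellular genes CYR61 (−1.33) and CTGF (−1.30), SAT1 (−1.29), the Notch ligand JAG1 (−1.27) and EMP1 (−1.20) were among the next largest falls.

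The hormone lists shifted in knockout cells as well. Of 38 genes raised by estrogen, 10 rose and 3 fell (11 up and 3 down adjusted over the list alone), with CA12 (1.18), TGFA (1.51), SLC7A5 (1.15) and NRIP1 (0.76) up, and the set was up (median 0.12, camera adjusted p = 1.6e-07; adjusted p = 0.564 with an estimated correlation). Of 16 genes lowered by estrogen, 5 fell and 0 rose (0 up and 6 down adjusted over the list alone), among them TP53INP1 (−0.53), CCNG2 (−0.51) and YPEL3 (−0.35), and the set was down (median −0.24, camera adjusted p = 0.00016; adjusted p = 0.564 with an estimated correlation). ESR1 fell by 0.35 ± 0.09 with an adjusted p of 0.0498, and without the 2 arrays the change was −0.24 (adjusted p = 0.086). Of 36 mitosis genes, 0 rose and 1 fell, KIF23 (−0.30), with 3 up and 3 down adjusted over the list alone (camera adjusted p = 0.937), and of 39 replication genes 1 rose, UHRF1 (0.50), and 0 fell (camera adjusted p = 0.937).

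Several adhesion, mesenchymal and immune genes fell in knockout cells given estradiol. Epithelial junction genes counted 1 up and 10 down of 30 (1 up and 11 down adjusted over the list alone), with JUP (−0.75), CLDN1 (−0.74), DSP (−0.44) and GRHL2 (−0.40) down (median −0.13, camera adjusted p = 0.0022; adjusted p = 0.807 with an estimated correlation). Mesenchymal genes counted 0 up and 5 down of 20 (0 up and 8 down adjusted over the list alone), with the integrins ITGB3 (−0.79) and ITGAV (−0.50), TPM1 (−0.69) and CALD1 (−0.56) down (median −0.22, camera adjusted p = 0.00024; adjusted p = 0.564 with an estimated correlation). TGF-beta and BMP targets counted 0 up and 4 down of 20 (0 up and 5 down adjusted over the list alone), including CTGF, TGFB2 (−0.56) and LTBP3 (−0.60) (median −0.34, camera adjusted p = 0.0019; adjusted p = 0.564 with an estimated correlation). Antigen presentation counted 1 up and 3 down of 14 (1 up and 7 down adjusted over the list alone): HLA-DMA (−0.84) and HLA-E (−0.81) were among the falls and the immunoproteasome subunit PSMB10 rose (0.47; median −0.26, camera adjusted p = 0.0076; adjusted p = 0.807 with an estimated correlation). Interferon-response genes counted 0 up and 3 down of 27 (0 up and 10 down adjusted over the list alone), with IFITM1 (−0.56), IFITM3 (−0.46) and STAT2 (−0.40) down (median −0.10, camera adjusted p = 0.0016; adjusted p = 0.773 with an estimated correlation). Immediate early genes counted 0 up and 6 down of 27 (0 up and 7 down adjusted over the list alone), with BTG2 (−0.57) and KLF2 (−0.40) down (median −0.11, or −0.0733 after quantile normalization; camera adjusted p = 0.00034; adjusted p = 0.627 with an estimated correlation). Fibroblast and stromal markers counted 0 up and 3 down of 7, without a shift of the list (camera adjusted p = 0.068). Knockout estradiol 1, which carried the parental profile, is included in these values. Without the 2 arrays, the medians were −0.237 (mesenchymal), −0.24 (TGF-beta and BMP), −0.182 (antigen presentation) and −0.0809 (interferon). These lists were higher in the untreated knockout line, whose arrays enter both comparisons, so the falls can hold shared chance values. With the 2 arrays left out, parental cells showed such falls too: 0 up and 6 down of 20 mesenchymal genes (1 up and 11 down adjusted over the list alone; median −0.20, camera adjusted p = 0.0103) and 0 up and 9 down of 20 TGF-beta and BMP targets (0 up and 10 down adjusted over the list alone; median −0.24, camera adjusted p = 0.0128), each with adjusted p = 0.984 with an estimated correlation.

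A few genes of protein synthesis and respiration rose in knockout cells given estradiol. Ribosomal protein genes counted 3 up and 0 down of 46 (3 up and 0 down adjusted over the list alone), RPS21 (0.39), RPL7 (0.32) and RPL24 (0.28), and the set was up (median 0.14, or 0.077 after quantile normalization; camera adjusted p = 7.1e-11; adjusted p = 0.564 with an estimated correlation). Respiratory chain genes counted 4 up and 0 down of 34 (5 up and 0 down adjusted over the list alone), with SDHD (0.34), ATP5G1 (0.34), COX7B (0.30) and SDHB (0.26) up (median 0.11, camera adjusted p = 3.2e-07; adjusted p = 0.564 with an estimated correlation). Camera compares a list with the other genes, most of whose calls were falls, and fry, which tests a list against no change, called neither (adjusted p = 0.154 and 0.13). Both lists were lower in the untreated knockout line, whose arrays enter both comparisons, so these rises can hold shared chance values. In all, estradiol changed 763 genes in knockout cells, 233 up and 530 down (30.5% rises), and after quantile normalization 472 of 1071 calls were rises (44.1%). Leaving the 2 arrays out gave 1337 genes, 499 up and 838 down, and single arrays left out gave 323 to 1105 genes, the fewest without the array labelled knockout untreated replicate 1.

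**Figure D4:**
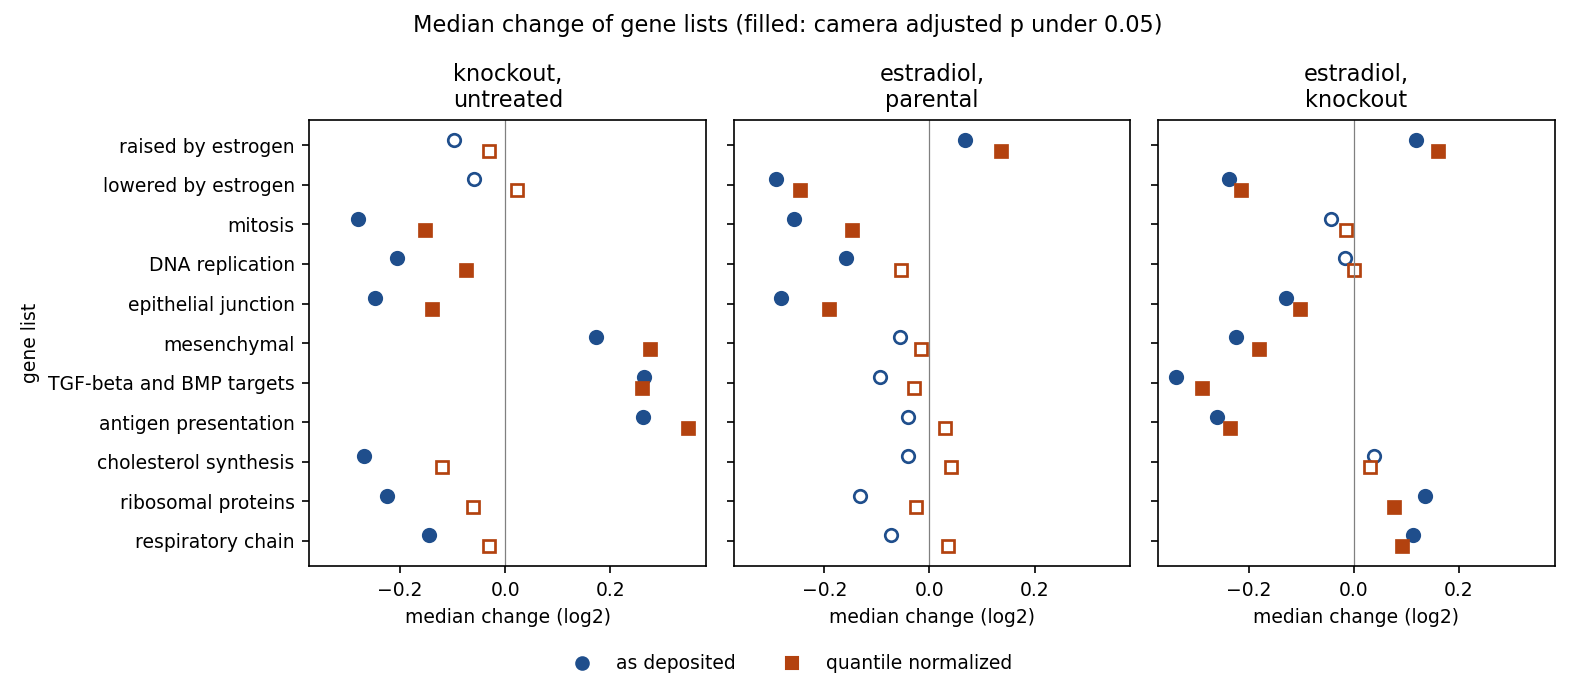
Median change (log2) of 11 gene lists in 3 comparisons, with circles for the deposited values and squares for quantile-normalized values, filled where camera's adjusted p was under 0.05. Filled lists kept their side of 0 under both scalings, while several open ones, such as cholesterol synthesis after estradiol in parental cells, did not.

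The responses of both lines to estradiol had much in common. A total of 362 genes were called in the same direction in both lines and 4 in opposite directions, where 33.7 would be expected if the calls were independent. The fit of 10 arrays gave 617 and 14, with 84.6 expected. Across all genes tested, the responses had r = 0.475, and genes are not independent replicates. Over the 1376 genes called in parental cells, the knockout response had the same sign for 85.3% and a slope of 0.650 on the parental response (jackknife SE 0.151), or 0.605 without the 2 arrays. Over the 763 genes called in knockout cells the sign was the same for 90.8%. The parental response then had a slope of 0.770 on the knockout response, or 0.795 without the 2 arrays. Choosing genes by 1 line's values lowers the slope of the other, so neither slope by itself shows a weaker response of 1 line.

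The interaction asked whether the response to estradiol differed between the lines. With the labels as deposited, 1 gene was called, LOC730255, an uncharacterized locus named after its values were seen, with a response of −0.26 in parental and 0.47 in knockout cells (difference 0.72 ± 0.09). There were 2069 genes with an unadjusted p under 0.05. The fit of 10 arrays called 148 genes, 95 with a positive and 53 with a negative difference. That balance turned with quantile normalization as well, which gave 82 positive and 155 negative differences among 237 genes. Several of these responded in parental cells and hardly in knockout cells. TNFRSF14, a receptor of immune signalling, went from 8.38 to 9.95 in parental and from 7.06 to 7.16 in knockout cells (−1.47 ± 0.13, n = 3 untreated and n = 2 with estradiol per line, adjusted p = 2.5e-05). MUC5AC went from 8.75 to 10.17 and from 6.89 to 6.97 (−1.34 ± 0.12, adjusted p = 2.5e-05), and the collagen COL15A1 from 6.74 to 7.74 and from 6.75 to 6.74 (−1.01 ± 0.10, adjusted p = 0.00013). In knockout cells MUC5AC and COL15A1 read close to the array medians of 6.78 to 6.86, where falls and small rises can hardly be measured. These differences therefore do not give the exact size of a lost response. COL15A1 read as low in untreated parental cells (6.74), and its rise to 7.74 was measured from there. MLPH (−1.26 ± 0.10) and ALPPL2 (−1.02 ± 0.13) rose in both lines, and more in parental cells. With the 2 arrays included, the interaction was 0.40 for TNFRSF14 (adjusted p = 0.93) and 0.79 for MUC5AC (adjusted p = 0.87), so both signs turned when they were left out.

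As a set, mitosis genes fell with estradiol in parental cells (median −0.26) and hardly changed in knockout cells (−0.04). The median difference was 0.24 (camera adjusted p = 1.4e-09, or 0.564 with an estimated correlation). Of the members, 0 were called over all genes, and 11 up and 0 down adjusted over the list alone. The shift passed the threshold after quantile normalization (0.143, adjusted p = 1.6e-05) and without the 2 arrays (0.219, adjusted p = 5.7e-07), where PLK1, a mitotic kinase, was called (0.51, adjusted p = 0.043). The untreated parental arrays enter this difference, the fall in parental cells and the comparison of the untreated lines. These mitosis shifts are therefore not independent, and those 2 fits keep the same arrays. Without the 2 arrays, mitosis genes did not shift between the lines in estradiol (median −0.0444, camera adjusted p = 0.119). Mesenchymal genes fell more in knockout cells (median −0.22) than in parental cells (−0.06). The untreated knockout arrays, where this list was higher, enter both the fall in knockout cells and the difference. The median difference was −0.19 (camera adjusted p = 0.0014, or 0.564 with an estimated correlation). It was also called by camera after quantile normalization (adjusted p = 0.0010) and without the 2 arrays (−0.061, adjusted p = 0.015). Without them the medians were −0.24 in knockout and −0.20 in parental cells, and 1 member, ITGAV (−0.58, adjusted p = 0.039), was called. The fibroblast marker COL5A1 (−0.52, adjusted p = 0.030) was called in that fit too. In the same fit the inducible cyclooxygenase PTGS2 (−0.69, adjusted p = 0.0066) and the membrane estrogen receptor gene GPER (−0.67, adjusted p = 0.0049) responded less in knockout cells. ESR1 did not pass the test of the difference with the 2 arrays (0.34 ± 0.13, adjusted p = 0.36) or without them (0.47, adjusted p = 0.067).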

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

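The tests of an exchange of labels, of mixed and of incompletely edited cells, and the fits without 2 arrays, were chosen only after the result was seen, and the other tests were chosen before.

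The array labelled parental estradiol replicate 3 and the array labelled knockout estradiol replicate 1 carried the MTDH level and the profile of the other line. Differences in brightness argue poorly for this, since after quantile normalization their positions between the untreated lines (0 parental, 1 knockout) were 0.874 and 0.0747. An exchange of the labels of these 2 arrays would need 1 array beyond 0.8 and the other below 0.2: they stood at 0.865 and 0.235, so the second missed its bound, while the other estradiol arrays of the parental line also stood at 0.147 and 0.185. Measured from the other estradiol arrays of the opposite line, the distances were 0.0685 and −0.0548, within what an exchange could give. The positions after quantile normalization, 0.874 and 0.0747, lay within both bounds. MTDH of parental estradiol 3 lay 0.385 above the highest of the other 5 arrays at the knockout level. Parental cells mixed into that sample would need a share of 0.0923 for this. The 14 genes far lower in knockout cells gave a median share of 0.0133 (quartiles 0.00152 and 0.0404), which argues against mixing as its source. Incompletely edited cells may still account for it and stay open, because no genotype of the samples is given. They would also put MTDH of knockout estradiol 1 between the lines. It lay 0.162 above the lowest of the other 5 arrays at the parental level, within their range.

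The interaction marked LOC730255 (0.7243) and, without the 2 arrays, 148 genes as responding differently to estradiol in the lines. If the 2 arrays were the source of the call for LOC730255, it would end without them, and 1 of 1 gene was called again. The call was fragile, however: 0 genes were called without parental estradiol 3 alone, and 0 to 3 with any single array left out. The slope of the interaction on the untreated knockout effect, −0.733 with the 2 arrays and −0.325 without, decides nothing, since the interaction holds that effect with its sign turned. Of 100 splits of the estradiol labels within lines, 3 gave as many genes, the labelled one included, which does not exclude chance, because splits that mix treated and untreated arrays widen the spread and the call was lost after quantile normalization (0 genes). The highest other split gave 2086 genes, with estradiol and untreated labels inverted in the knockout line, which points to the response shared by both lines as a structure of the samples. A different response of the knockout line, from MTDH or the clone, is a candidate explanation that stays open and untested, and quantile normalization without the 2 arrays gave 237 genes with 34.6% positive differences in place of 64.2%.

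Without the 2 arrays, a test of the difference, knockout response minus parental response, marked FCF1 (1.148), OAZ2 (0.8511), PTMA (0.7934) and NDST1 (0.7586) as positive. It also marked TMSL3 (0.712) and FTHL3 (0.7046), identifiers of pseudogenes nearly identical to TMSB4X and FTH1, so which transcript they read is uncertain. On the other side it marked TNFRSF14 (−1.473), MUC5AC (−1.343), MLPH (−1.265), SNORD3A (−1.023), ALPPL2 (−1.019) and COL15A1 (−1.01). With all arrays, camera marked lists with a positive difference, which a weaker fall in knockout cells can also give. Among them were mitosis (0.237) and DNA replication (0.145, camera adjusted p = 0.0023, or 0.807 with an estimated correlation). Ribosomal proteins (0.253, or 0.0873 after quantile normalization, with camera adjusted p = 2.9e-11, or 0.564 with an estimated correlation) and the respiratory chain (0.177, camera adjusted p = 1.6e-05, or 0.675 with an estimated correlation) were others. Hypoxia and glycolysis (0.137, camera adjusted p = 0.033; adjusted p = 0.923 with an estimated correlation) and epithelial junction (0.163, camera adjusted p = 0.035; adjusted p = 0.961 with an estimated correlation) were marked the same way. Lists with a negative difference were mesenchymal genes (−0.192), TGF-beta and BMP targets (−0.177, camera adjusted p = 0.0057, or 0.634 with an estimated correlation) and fibroblast markers (−0.126, camera adjusted p = 0.0079, or 0.564 with an estimated correlation). Antigen presentation (−0.231, camera adjusted p = 0.0024; adjusted p = 0.791 with an estimated correlation), the interferon response (−0.0745, camera adjusted p = 0.019; adjusted p = 0.856 with an estimated correlation) and immediate early genes (−0.0497, camera adjusted p = 0.033; adjusted p = 0.807 with an estimated correlation) were marked down too. In the fit without the 2 arrays, DNA replication, antigen presentation, TGF-beta and BMP targets, the interferon response and epithelial junction were no longer called, and after quantile normalization the respiratory chain, DNA replication, hypoxia and epithelial junction were not.

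For the other comparisons the 10 possible splits of 3 against 3 arrays are too few for a share under 0.05. Between the untreated lines the labelled split gave 2152 genes and the highest other 0, with 1 of 10 splits as large. Estradiol gave 1376 genes in parental cells and 763 in knockout cells, each with 0 in the highest other split and 1 of 10 splits as large. With estradiol, the labelled comparison of the lines gave 0 genes, so that 10 of 10 splits gave as many, and the highest other gave 2917. That was the split that exchanges the 2 arrays, which points to a structure of the samples that the labels do not follow.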

How the results depend on the processing

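The fits without 2 arrays, with and without quantile normalization, were chosen only after the result was seen. Results are given in the order knockout effect untreated, knockout effect with estradiol, estradiol in parental cells, estradiol in knockout cells, and interaction, and where a value differed from the one reported the cause was not tested unless the setting itself shows it. All alternatives called 0 genes for the knockout effect with estradiol except the fits without the 2 arrays, and none turned the direction of MTDH. Without the 2 arrays the counts were 3844, 1926, 2114, 1337 and 148, and with quantile normalization as well 3671, 2873, 1411, 1909 and 237. MTDH with estradiol was then −2.398 and −2.356. Quantile normalization alone gave 886 genes for estradiol in parental cells and 0 for the interaction. Array weights gave 4432, 0, 3027, 1048 and 12 genes, and fits of the 6 arrays compared gave 3801 between the untreated lines. A minimum of 1.5-fold left 365, 0, 231, 181 and 1, and a threshold of 0.01 left 402, 0, 463, 271 and 0, both by construction. The interaction alone moved by over 1.5 times with no filter (2 genes), the stricter filter (0), median centring (8), the trended and robust prior (0) and the replicate block (5). With the replicate block the other counts were 2571, 0, 1556 and 823, though whether the numbers pair the arrays is not settled. MTDH untreated was −2.567 (adjusted p = 0.0668) with the trended and robust prior. Leaving out 1 array at a time gave 435 to 2826, 0 to 0, 508 to 1707, 323 to 1105 and 0 to 3 genes, MTDH of −2.744 to −2.417 untreated and −1.758 to −0.5351 with estradiol, and an estradiol slope of 0.571 to 0.731. Counts moved by over 1.5 times between the untreated lines without parental untreated 1 (854) or 2 (435) or knockout untreated 1 (1277), 2 (460) or 3 (650). They did so for estradiol in parental cells without parental untreated 1 (644) or 2 (508) or parental estradiol 1 (768) or 2 (693), and in knockout cells without knockout untreated 1 (323), 2 (348) or 3 (327) or knockout estradiol 3 (434). Of 145 list tests 48 were called by camera at the preset correlation, 0 with an estimated correlation and 18 by fry. Of those 48, 34 were called in the same direction after quantile normalization, 47 after centring, 46 with the block, 39 without the 2 arrays and 32 with both changes. Of 216 calls of named genes, 170 were called again after quantile normalization, 178 with the trended and robust prior, 212 without the 2 arrays and 124 to 211 with 1 array left out, with 0 reversed. Values not called with all arrays turned sign for the interaction of TNFRSF14 (0.40 to −1.473, and −1.557 with quantile normalization), MUC5AC (0.79 to −1.343 and −1.451) and ADORA1 (0.04 to −0.5495 and −0.6377) without the 2 arrays. NKD2 (−0.5175) and SPRY2 (−0.461) did so with both changes, and the epithelial junction list, called up with all arrays, tested down without the 2 arrays (median 0.1043, camera adjusted p = 0.739) and with both changes (median 0.009543, camera adjusted p = 0.129); the cause was not tested. Median and test also differed in sign for Wnt targets (median −0.0263, test up, camera adjusted p = 0.0339) and the unfolded protein list (median −0.0149, test up, camera adjusted p = 0.00497) after estradiol in parental cells without the 2 arrays, and there too for immediate early genes in the interaction (median 0.0115, test down, camera adjusted p = 0.0159); with an estimated correlation their adjusted p was 0.981 to 0.984. Alternatives for combining probes and for a pseudocount were not run, since the table holds combined log2 values. The lowest values of each array limit how low a gene can read, SPON1 in untreated knockout cells (6.78) included.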

Other observations

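The tests of neighbouring genes were chosen before the result was seen, and the fit without 2 arrays was chosen only after the result was seen.

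Some genes of endometrial epithelium were lower in the knockout line. Of 15 tested endometrial and Müllerian genes, 7 fell and 1 rose without estradiol (1 up and 7 down adjusted over the list alone), including MUC16, the secretoglobin SCGB2A1 (−1.93, adjusted p = 0.0055), the signalling ligand WNT7A (−1.34, adjusted p = 0.027) and the transcription factor SOX17 (−1.14, adjusted p = 0.0072). The list did not pass camera with all arrays (adjusted p = 0.106) and did without the 2 arrays (2 up and 7 down, adjusted p = 0.00036; adjusted p = 0.981 with an estimated correlation). With estradiol and without the 2 arrays, 5 fell and 0 rose, among them WFDC2 (−1.63), WNT7A (−1.38) and SCGB2A1 (−1.23). Ribosomal protein genes fell in untreated knockout cells in 16 of 46, among them RPL15 (−0.47), RPS3 (−0.40) and RPL7 (−0.38), with 0 up and 19 down adjusted over the list alone (median −0.23, camera adjusted p = 1.4e-06; adjusted p = 0.741 with an estimated correlation), a shift that missed the threshold after quantile normalization (median −0.0605, adjusted p = 0.053). Respiratory chain genes fell in 9 of 34, among them COX7B (−0.40), UQCRC2 (−0.40) and COX5A (−0.33), with 0 up and 12 down adjusted over the list alone (median −0.15, camera adjusted p = 0.00034; adjusted p = 0.773 with an estimated correlation), and not after quantile normalization (median −0.0298, adjusted p = 0.84). In knockout cells given estradiol, genes of the unfolded protein and integrated stress responses counted 4 up and 0 down of 38 (5 up and 4 down adjusted over the list alone), with CEBPB (0.98), SLC3A2 (0.71) and the chaperone cofactor SDF2L1 (0.33) up (median 0.07, camera adjusted p = 0.012; adjusted p = 0.856 with an estimated correlation; fry adjusted p = 0.409), and not after quantile normalization (adjusted p = 0.12).

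Other lists did not shift between the untreated lines by camera. Hypoxia and glycolysis counted 1 up and 7 down of 32 (4 up and 8 down adjusted over the list alone; adjusted p = 0.423), oxidative stress genes of the NRF2 response 3 up and 5 down of 24 (4 up and 7 down adjusted over the list alone; adjusted p = 0.94), and growth factors and their receptors 2 up and 3 down of 31 (6 up and 8 down adjusted over the list alone; adjusted p = 0.663). Targets of p53 counted 1 up and 3 down of 25 (adjusted p = 0.94), Wnt targets 3 up and 2 down of 16 (adjusted p = 0.165), unfolded protein genes 0 up and 4 down of 38 (adjusted p = 0.979), fatty acid genes 0 up and 2 down of 19 (adjusted p = 0.856) and apoptosis genes 0 up and 2 down of 25 (adjusted p = 0.607). Markers of other cells were few: leukocyte markers counted 0 up and 1 down of 9 (adjusted p = 0.747), luminal breast genes 0 up and 1 down of 9 (adjusted p = 0.653), and endothelial and red cell markers, with 3 tested members, 0 up and 0 down. Targets of p53 shifted down relative to the other genes in knockout cells given estradiol (median −0.10, camera adjusted p = 0.022, or 0.807 with an estimated correlation). Of 25 members, 0 rose and 3 fell (0 up and 4 down adjusted over the list alone), with BTG2 and DDB2 at −0.57 and −0.30. Fry, which tests a list against no change, did not call it (adjusted p = 0.157). The camera shift missed the threshold after quantile normalization (adjusted p = 0.057) and without the 2 arrays (adjusted p = 0.089).

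Some neighbouring genes differed together between the lines: of the 10 tested genes nearest to MTDH on chromosome 8, PTDSS1 (−0.42, adjusted p = 0.022), PGCP (−0.72, adjusted p = 0.021) and LAPTM4B (−0.47, adjusted p = 0.031) fell without estradiol, named here as called neighbours after their values were seen. Not called were SDC2 (−0.55), MATN2 (−0.27), RPL30 (−0.15), UQCRB (−0.07) and MTERFD1 (−0.05), and on the higher side SNORA72 (0.14) and C8ORF47 (0.24). Without the 2 arrays, SDC2 (adjusted p = 0.0073) and MATN2 (adjusted p = 0.036) were also called down and C8ORF47 (adjusted p = 0.011) up. The mean of the 10 genes, −0.232, stood at the 2.95 percentile of 13295 such neighbourhoods, or at 2.59 with estradiol and without the 2 arrays. There SDC2, PGCP, LAPTM4B and MATN2 were called down and PTDSS1 was not called (−0.23, adjusted p = 0.26). UQCRB (0.18), RPL30 (0.13), SNORA72 (0.14) and C8ORF47 (0.21) read higher there, without a call. Over windows of 30 genes, the largest mean change was 0.275 in size (−0.275, from C17ORF28 to MRPL38 on chromosome 17), beyond the 95th of 100 shuffles of gene order (0.228). It was −0.1194 with estradiol and without the 2 arrays, while the 3 other windows beyond that limit, on chromosomes 9 and 19, had −0.1894, −0.2438 and −0.1804 there. The windows counted started every 10 genes, so those on the same chromosome can overlap and need not be separate segments. Array scaling is argued against as the whole source: after quantile normalization the mean beside MTDH was smaller in size, −0.137, but at the 4.1 percentile, and the largest window, from EDF1 to ENTPD8 on chromosome 9, was 0.214 in size against 0.188 in shuffles. Loss of chromosome segments in the knockout clone is a candidate explanation that stays open. It has less behind it for the window on chromosome 17, whose change was smaller with estradiol, and beside MTDH not all genes were lower. Shared regulation of neighbours was not tested.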
